A study of Mus musculus with 24 samples.

How the data were processed

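Right ventricular RNA of 24 mouse samples was measured on 1-colour Agilent arrays, 1 array per sample. Per the labels' protocols, RNA was extracted with a column kit, 0.5 ug was amplified and labelled with Cy3, and the treatment was either sham surgery or surgery that puts a pressure and volume load on the right ventricle (PSPI). Per the file headers, the arrays are of 1 design with coordinates on the mouse build mm9 and were read with Agilent Feature Extraction 10.7.3.1 using spatial detrending. The deposited scanner files hold intensity values per spot on a linear scale, background subtracted by Feature Extraction and not scaled between arrays. The deposited table of the whole series, whose name calls it normalized, also holds intensity values. Its value equalled the net signal of the scanner file, within a relative tolerance of 0.001, for 62976 of 62976 spots on each array, so no scaling between arrays was found in it. It was not background subtracted, and no further step by the authors is stated.

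Groups were taken from the titles: 10 sham samples, 5 PSPI samples of month 1, 5 of month 2 and 4 of month 3. Sham titles give no month, so each month was set against all 10 shams, although the design text gives 4 to 5 controls. Nothing in the labels says that samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The arrays lay on 3 slides. Slide 1 held 7 shams and 1 month 1 sample. Slide 2 held 3 month 1, 4 month 2 and 1 month 3 samples. Slide 3 held 3 shams, 1 sample each of months 1 and 2, and 3 of month 3.

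Control spots and outlier spots (143 to 290 per array) were left out and spots of 1 probe were averaged. Each array's log2 processed signal was reduced by its 75th percentile, taken over the 16963 probes well above background on all 24 arrays. That rule is meant for arrays on which under 50% of probes are detected, which held on 22 of 24 arrays (36.1% to 56.1% of probes per array, median 41.0%). The percentile over all probes is given as an alternative, and both versions had been seen when this was settled. Of 55681 probes, 21038 were kept, being well above background on every array of at least 1 group. Names came from the file's accession through a gene table of assembly GRCm38.p6, from which no coordinate was used (26582 probes), from a current symbol (2602) or an older symbol (492). The file's own name was kept for 1421 probes, and 24584 had none. A gene was represented by its kept probe with the highest mean log2 signal over all arrays, which left 12472 genes, 9636 with 1 kept probe and 2836 with more. Kept probes of 1 gene were called in opposite directions for 22 of 3315 genes with a called probe over all months, 9 of 1988 in month 2 and 56 of 5305 in month 3.

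Genes were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 model of the 4 group means without covariates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a gene below is from that model, every ± after a log2 change is its standard error, and all tests are two-sided. The 36 gene lists, fixed before the data were examined, were tested with camera (inter-gene correlation preset at 0.01, adjusted over the 36 lists), and again with an estimated correlation. A gene not well above background on any array of a group is given as at least N-fold: the brighter group's mean against the mean of, per array, the higher of the probe's own value and the lowest value of any probe well above background. The named genes follow a rule fixed before the data were examined. It took genes with a plain symbol past the threshold, ranked by log2 change: 12 up and 12 down for all months, 8 and 8 for each month against sham, and 6 and 6 between months. It also took up to 4 members with the smallest p of each list and, always, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1 and Postn. The text names part of these genes, chosen after their values were seen.

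On simulated data with 200 genes changed, the model run on 12472 genes recovered for all months 98.5% of 2-fold changes and 100% of larger ones, with 4.33% of calls false. For month 1 it recovered 95.5% of 2-fold changes (4.41% of calls false), for month 2 92.5% (6.28%), for month 3 94.0% (3.47%) and for month 3 against month 2 89.6% (7.28%). In the simulation camera called the 1 shifted list of 36 and none of the others. Each gene and array was drawn independently, so the simulation held no correlation between genes and no arrays that resemble each other. Its error rates therefore need not hold in the real data. Random splits of the real arrays called a median of 9 of 36 lists over all months and 10 in month 1.

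Alternatives fixed before the data were examined were other scalings, normexp background correction with offset 50, the deposited table, other filters and probe rules, array weights, a trended robust fit, slide as a fixed or random block, slide 3 alone, a replicate block, only the groups compared, and leaving out each array. Alternatives added after seeing the data were the percentile over all probes, averaging arrays that nearly coincide, leaving out month 3, and leaving out 1250 genes with repeat, multicopy or clone names or repeat probes (11222 kept). For the averaging, the distance limit of 0.3 over the 200 most variable genes was set after pair distances were seen (500 genes gave the same 8 pairs), and the 24 arrays were kept as the basis before the averaged counts were seen. The precision is limited by the number of arrays; the 75th percentile lay between 899 and 3916 intensity units, no spot was saturated, and spots of 1 probe differed by a log2 SD of 0.046 to 0.094. Matplotlib 3.10.9 drew the figures.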

Results

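Gene expression was measured in the right ventricle of 24 mouse samples: 10 after sham surgery and 14 after PSPI, a surgery that loads the right ventricle with pressure and volume, taken at month 1 (n = 5), month 2 (n = 5) and month 3 (n = 4). The design text asks how overloaded right ventricles differ from control ones. Levels are log2 normalized signals, and 12472 genes were tested. The first principal component took 32.0% of the variance and the second 24.0%.

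Features of the samples that the labels do not give run beside every comparison. In 8 of 276 pairs, arrays of the same group nearly coincided (distance up to 0.27, against at least 0.40 for other pairs and 0.46 across groups). Of these 6 lay on different slides. The arrays were Sham 3, 4 and 10, Sham 1 and 5, Sham 7 and 9, PSPI month 1 samples 1 and 5, month 2 samples 1 and 5, and month 3 samples 2 and 3. The labels name no repeated sample, and all 24 arrays were kept. The design text gives 4 to 5 control samples, while 10 shams are deposited. Each count of changed genes, but not those at least 2-fold, is given also with such arrays averaged to 17 samples (6, 4, 4 and 3). Myh7, the slow myosin heavy chain that rises in loaded mouse ventricle, lay at 1.63 to 2.54 on 9 arrays and at 4.68 to 5.93 on 15. The higher level held 4 shams (6 to 9), month 1 samples 1 and 5, and all samples of months 2 and 3. The first principal component parted the same arrays, the 9 at -27.3 to -20.8 and the 15 at -2.11 to 35.6. The largest part of the variance thus ran across the labels of sham and month 1. The score of a list on each array, the mean of its members after centring each gene, parted the same 9 and 15 arrays for 7 of 36 lists, of which the hypertrophy list holds Myh7 itself. These levels were read from the measured values, so the ranges are given without a test. The 7 were hypertrophy, collagen, fatty acid, calcium handling, beta-adrenergic, hypoxia and apoptosis genes. Within slide 3, months 1 and 2 have 1 array each, so a value within slide 3 rests on 1 array for these months. Slide is also tied to the Myh7 level. The PSPI arrays at the lower level, month 1 samples 2 to 4, all lie on slide 2, which holds no sham. The PSPI arrays of slides 1 and 3 all stand at the higher level, while Sham 5 and 10 of slide 3 stand at the lower. Larger values with slide as a block or within slide 3 are therefore no separate support for lists that follow Myh7.

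**Figure D1:**
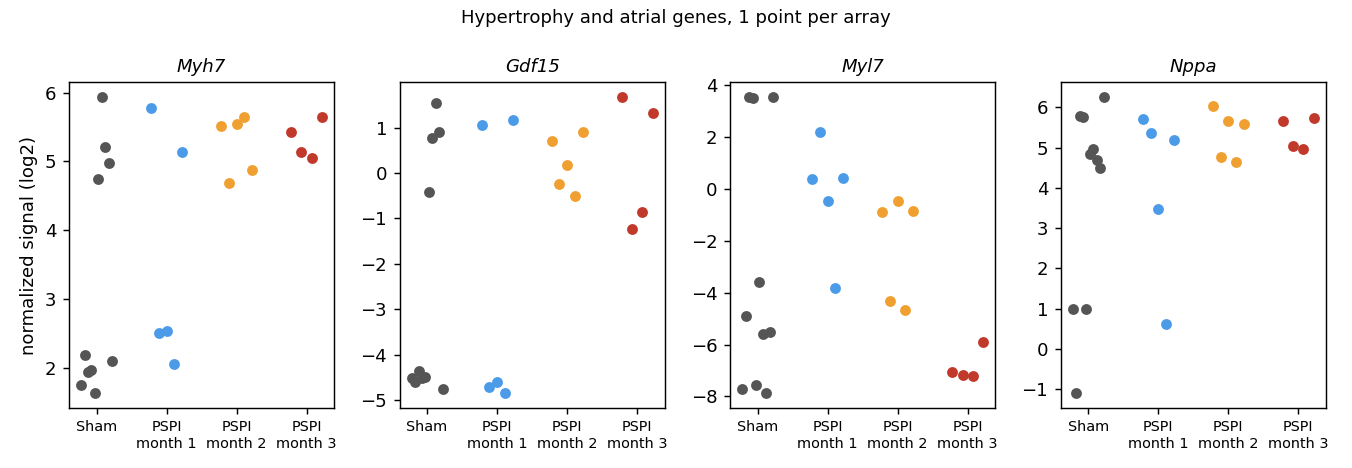
Normalized signal (log2, vertical axis) of Myh7, Gdf15, Myl7 and Nppa in each of the 24 arrays, grouped as sham and PSPI months 1 to 3, 1 point per array. Myh7 and Gdf15 each leave a gap (2.15 and 3.13 log2) that runs through the sham and the month 1 group, and Myl7 runs from -7.23 to -5.88 in month 3 and from -7.87 to 3.55 in sham.

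PSPI ventricles of all 3 months, weighted equally, were set against sham. Inflammatory genes were among the largest rises. S100a8, a subunit of calprotectin abundant in neutrophils and monocytes, rose 5.80-fold (log2 2.54 ± 0.33, adjusted p = 3.92e-05). Its level went from -6.27 ± 0.89 (SD, n = 10) in sham to -4.40 ± 0.78 (n = 5), -3.39 ± 0.53 (n = 5) and -3.40 ± 1.08 (n = 4) in months 1 to 3. In 14 of 14 PSPI arrays it lay above every sham. Its partner S100a9 rose by 2.48 ± 0.50, and Ccl8, a chemokine that attracts monocytes, by 1.89 ± 0.20 (adjusted p = 7.58e-06, 13 of 14 arrays above every sham). Sfrp1, a secreted antagonist of Wnt signalling, rose by 0.94 ± 0.11 (adjusted p = 1.51e-05) and lay above every sham in 14 of 14 arrays. The probes lie at 90473778 to 90473837 of chromosome 3 (S100a8), 81930108 to 81930167 of chromosome 11 (Ccl8) and 24559438 to 24559497 of chromosome 8 (Sfrp1) in mm9; exon and UTR were not assigned here.

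Further large rises over all months were those of Syt13 of the synaptotagmin family (2.59 ± 0.50), Nrip3 (2.04 ± 0.46), the chitinase-like Chil1 of macrophages and neutrophils (1.96 ± 0.36) and Prg4, which encodes the joint and surface lubricant lubricin (1.92 ± 0.42). In sham these were measured well above background in 3 (Syt13), 2 (Nrip3), 4 (Chil1) and 10 (Prg4) of 10 arrays, and S100a8 in 5. The largest falls included Urah, an enzyme of uric acid breakdown (-1.70 ± 0.33), Aqp1, a water channel of endothelium (-1.28 ± 0.22), and Akap5, an anchor protein of protein kinase A (-1.27 ± 0.29). Lower too were the potassium channel gene Kcna1 (-1.35 ± 0.38) and Angpt1, the ligand of the endothelial receptor Tie2 (-1.21 ± 0.31). With close arrays averaged, Kcna1 (-0.99 ± 0.44, adjusted p = 0.169) and Angpt1 (-0.98 ± 0.37, adjusted p = 0.112) no longer passed, and Akap5 did not pass with slide as a block (-1.13 ± 0.45, adjusted p = 0.0868).

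In all, 3043 genes changed, 1359 up and 1684 down, of which 121 rose and 21 fell at least 2-fold. With close arrays averaged 771 changed, 766 of them among the 3043. The count was 1984 with slide as a block (1523 shared), 0 within slide 3 alone (limma, 4 residual degrees of freedom, 1641 at an unadjusted p under 0.05), and 1179 without month 3. The share of calls that were higher was 44.7%, but 27.6% with the percentile over all probes, 31.6% with quantile normalization, 61.1% with normexp, 61.9% in the deposited table and 54.8% without the filter, so which direction held more genes was not settled.

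**Figure D2:**
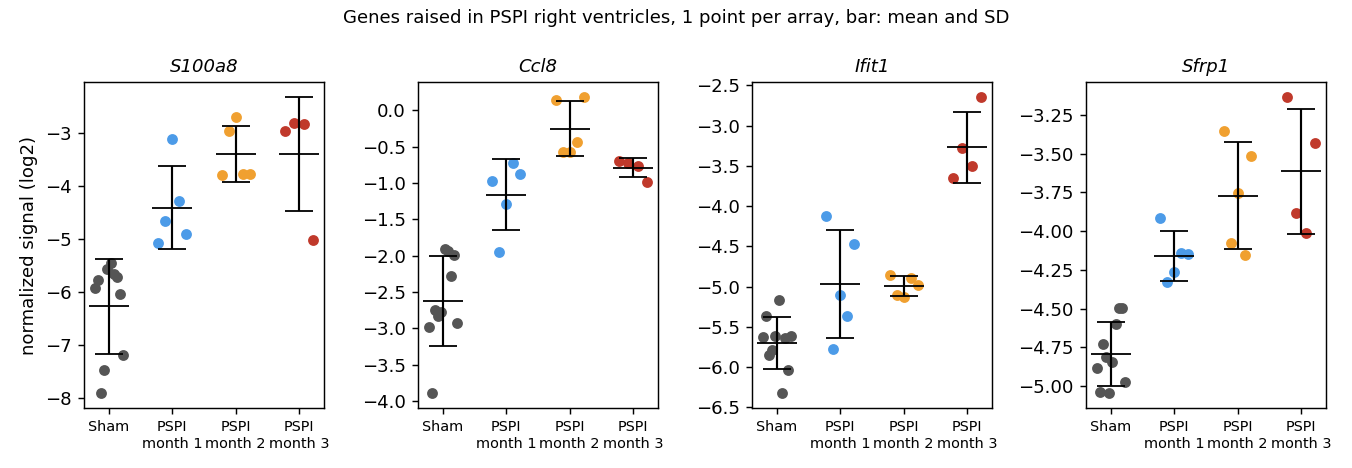
Normalized signal (log2, vertical axis) of S100a8, Ccl8, Ifit1 and Sfrp1 in each array, grouped as sham and PSPI months 1 to 3; bars give the mean and SD of each group. All 14 PSPI arrays lie above all 10 shams for S100a8 and Sfrp1, and Ifit1 has its highest group mean in month 3.

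By gene list, 5 immune lists were called higher over all months (camera, preset correlation), none of them with an estimated correlation, and T cell and B cell markers were not. Interferon response genes had 15 of 28 members higher and 0 lower over all genes, and 16 and 0 adjusted over the list alone. The interferon median was 0.35 (0.50 with slide as a block, 0.47 within slide 3), with adjusted p = 2.71e-08, and adjusted p = 0.257 with an estimated correlation. Examples were Ifit1, whose product binds foreign RNA (1.29 ± 0.16), Ifitm3, which restricts virus entry (0.52 ± 0.075), and Oasl2 (0.79 ± 0.13). Complement and antigen presentation genes had 8 of 21 members higher and 0 lower over all genes, and 11 and 0 adjusted over the list alone. The complement median was 0.36 (0.52 with slide as a block, 0.56 within slide 3), with adjusted p = 1.87e-06, and adjusted p = 0.0884 with an estimated correlation. C4b, a complement component, rose by 1.38 ± 0.26, and B2m and H2-D1, the chains of class I molecules, by 0.59 ± 0.081 and 0.56 ± 0.10. Macrophage and monocyte markers had 12 of 24 members higher and 0 lower over all genes, and 17 and 0 adjusted over the list alone. The macrophage median was 0.36 (0.40 with slide as a block, 0.49 within slide 3), with adjusted p = 2.16e-05, and adjusted p = 0.492 with an estimated correlation. C1qa (0.54 ± 0.11) and C1qc (0.42 ± 0.089), which encode chains of complement C1q, and the pore protein gene Mpeg1 (0.53 ± 0.12) were among those that rose, and C1qc did not pass with slide as a block (0.39 ± 0.14, adjusted p = 0.0574).

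Chemokine, cytokine and acute inflammation genes had 10 of 27 members higher and 1 lower over all genes, and 12 and 1 adjusted over the list alone. The chemokine median was 0.27 (0.30 with slide as a block, 0.46 within slide 3), with adjusted p = 0.000504, and adjusted p = 0.152 with an estimated correlation. Besides Ccl8, the acute phase protease inhibitor Serpina3n (1.09 ± 0.18) and the membrane-bound chemokine Cx3cl1 (0.70 ± 0.14) rose. Neutrophil and mast cell markers had 4 of 7 members higher and 0 lower over all genes, and 4 and 0 adjusted over the list alone. The neutrophil median was 0.47 (0.57 with slide as a block, 0.46 within slide 3), with adjusted p = 0.00161, and adjusted p = 0.0884 with an estimated correlation. Hdc, which makes histamine, rose by 0.83 ± 0.13. Antioxidant and oxidative stress genes had 9 of 37 members higher and 1 lower over all genes, and 11 and 1 adjusted over the list alone. The antioxidant median was 0.10 (0.093 with slide as a block, 0.027 within slide 3), with adjusted p = 0.0127, and adjusted p = 0.110 with an estimated correlation, and with slide as a block 0.146. The rises included heme oxygenase Hmox1 (0.70 ± 0.11), metallothionein Mt2 (1.04 ± 0.21) and glutathione peroxidase Gpx1 (0.40 ± 0.087).

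Lists of structure and growth were also called higher over all months, but 21 to 39 of 100 splits of the same arrays gave as small a p for each of the 6 that follow. The hypertrophy, collagen and apoptosis scores followed the 2 levels of Myh7, with collagen at -1.09 to -0.26 on the 9 arrays and at -0.21 to 0.86 on the other 15, Sham 6 to 9 among them. Hypertrophy and fetal program genes had 5 of 17 members higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone. The hypertrophy median was 0.81 (1.41 with slide as a block, 1.30 within slide 3), with adjusted p = 0.000195, and adjusted p = 0.727 with an estimated correlation. Fhl1, a LIM-domain protein of the sarcomere, rose by 0.90 ± 0.16. Myh7 (1.48 ± 0.55, adjusted p = 0.0524), Nppa (1.15 ± 0.76) and Nppb (1.09 ± 0.61), which encode natriuretic peptides, and skeletal actin Acta1 (0.73 ± 0.58) did not pass, and 4 of 10 shams lay at the higher Myh7 level. Nppa, also made in atria, lay at 5.76 to 6.25 in Sham 3, 4 and 10, where the atrial Myl7 stood at 3.50 to 3.55, and at -1.09 to 0.99 in Sham 1, 2 and 5. Myh6, the fast adult myosin, stood at 0.34 ± 0.27 (adjusted p = 0.380). Collagen and matrix genes had 5 of 38 members higher and 1 lower over all genes, and 2 and 0 adjusted over the list alone. The collagen median was 0.40 (0.62 with slide as a block, 0.63 within slide 3), with adjusted p = 0.00161, and adjusted p = 0.728 with an estimated correlation. The matrix glycoprotein Fbln2 rose by 0.67 ± 0.12, whereas Col1a1 (0.32 ± 0.26) and Col3a1 (0.13 ± 0.25), the main fibrillar collagens, did not pass. Periostin, Postn, stood at the threshold (1.21 ± 0.44, adjusted p = 0.0488, 1.02 ± 0.51, adjusted p = 0.223 with close arrays averaged, 0.0967 without Sham 5, and past it in 8 of 24 settings with 1 array left out).

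Matrix crosslinking and remodelling enzymes had 6 of 27 members higher and 1 lower over all genes, and 6 and 1 adjusted over the list alone. The remodelling median was 0.28 (0.46 with slide as a block, 0.40 within slide 3), with adjusted p = 0.00254, and adjusted p = 0.727 with an estimated correlation. Serpine2, a secreted protease inhibitor, rose by 0.60 ± 0.10. TGF-beta and BMP pathway genes had 7 of 29 members higher and 1 lower over all genes, and 8 and 1 adjusted over the list alone. The TGF-beta median was 0.20 (0.32 with slide as a block, 0.31 within slide 3), with adjusted p = 0.0173, and adjusted p = 0.728 with an estimated correlation. Tgfb1 itself rose by 0.56 ± 0.10. Cell cycle genes had 5 of 23 members higher and 2 lower over all genes, and 5 and 2 adjusted over the list alone. The cell cycle median was 0.34 (0.70 with slide as a block, 0.68 within slide 3), with adjusted p = 0.0113, and adjusted p = 0.728 with an estimated correlation, and with close arrays averaged 0.0506. Hmmr, a hyaluronan receptor of the mitotic spindle, rose by 0.63 ± 0.12. Apoptosis and p53 target genes had 6 of 25 members higher and 3 lower over all genes, and 6 and 4 adjusted over the list alone. The apoptosis median was 0.17 (0.33 with slide as a block, 0.31 within slide 3), with adjusted p = 0.0447, and adjusted p = 0.727 with an estimated correlation. This call was lost in 10 of 24 settings with 1 array left out (up to 0.0938, without Sham 1). Cdkn1a, the cell cycle inhibitor p21, rose by 1.15 ± 0.20.

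Lists of energy metabolism were called lower, with as small a p in 34 of 100 splits for the fatty acid and 44 for the citric acid cycle list. The fatty acid score also followed the 2 levels of Myh7, with 0.19 to 0.59 on the 9 arrays and -0.59 to -0.0065 on the other 15, Sham 6 to 9 among them. Fatty acid uptake and oxidation genes had 1 of 40 members higher and 14 lower over all genes, and 2 and 20 adjusted over the list alone. The fatty acid median was -0.28 (-0.46 with slide as a block, -0.46 within slide 3), with adjusted p = 0.000307, and adjusted p = 0.728 with an estimated correlation. Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, fell by 0.42 ± 0.094 and Acacb, an acetyl-CoA carboxylase that restrains mitochondrial fat import, by 0.48 ± 0.12, but neither passed with close arrays averaged (Etfdh -0.39 ± 0.12, adjusted p = 0.0569, Acacb -0.44 ± 0.15, adjusted p = 0.0750). Citric acid cycle genes had 0 of 22 members higher and 5 lower over all genes, and 0 and 5 adjusted over the list alone. The citric acid cycle median was -0.12 (-0.21 with slide as a block, -0.27 within slide 3), with adjusted p = 0.0387, and adjusted p = 0.804 with an estimated correlation. The call was lost in 9 of 24 settings with 1 array left out, up to 0.137 without PSPI month 3 sample 4. Sucla2, a subunit of succinyl-CoA ligase, fell by 0.29 ± 0.072. Endoplasmic reticulum stress genes had 1 of 24 members higher and 4 lower over all genes, and 1 and 4 adjusted over the list alone. The endoplasmic reticulum median was -0.15 (-0.10 with slide as a block, -0.043 within slide 3), with adjusted p = 0.0401, and adjusted p = 0.727 with an estimated correlation. This call was lost in 4 of 24 such settings (up to 0.0742, without Sham 8) and with slide as a block (0.157).

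The other 21 lists did not pass over all months. Median shifts were 0.14 for glucose uptake and glycolysis genes (adjusted p = 0.0512), 0.15 for fibroblast markers (0.0512) and -0.071 for respiratory chain and ATP synthase genes (0.107). They were 0.069 for hypoxia and angiogenesis genes (0.141), 0.16 for sarcomere genes of adult ventricle (0.143) and -0.22 for calcium handling and ion channel genes (0.167). Shifts were 0.053 for Wnt pathway genes (0.340), -0.20 for lung epithelium markers (0.373), 0.10 for smooth muscle and pericyte markers (0.425) and 0.20 for T cell and NK cell markers (0.433). Values were -0.037 for atrial cardiomyocyte markers (0.449), 0.10 for immediate early genes (0.502), -0.14 for circadian clock genes (0.660) and 0.50 for B cell and plasma cell markers (0.765). Erythroid and blood cell markers stood at 0.058 (0.765), beta-adrenergic and renin-angiotensin genes at -0.12 (0.794) and neuronal and Schwann cell markers at -0.17 (0.959). The median and the test or mean had different signs for endothelial (0.0098, 0.765), adipocyte (-0.044, 0.794), epicardial and mesothelial (0.012, 0.959) and skeletal muscle markers (0.02, 0.959). Single members passed: Ace, which makes angiotensin II, rose by 0.73 ± 0.10, while the beta-adrenergic receptor gene Adrb1 (-0.71 ± 0.14) and Kcnd2, a channel of the transient outward current (-0.85 ± 0.18), fell. Pfkl of glycolysis (0.65 ± 0.10) and the stress-responsive Ndrg1 (0.45 ± 0.069) rose. In sum 12 lists were called higher and 3 lower (15, and 13 with close arrays averaged), 0 with an estimated correlation, and 13 of 100 splits of the same arrays called as many lists, so this number did not stand beyond other splits.

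Month 1 against sham asked what differs early, and no single gene passed. Of 8 lists called (15 with close arrays averaged), 4 were immune, while T cell, B cell and neutrophil markers were not called. As many lists were called in 66 of 100 splits of the same arrays. Complement and antigen presentation genes had 0 of 21 members higher and 0 lower over all genes, and 12 and 0 adjusted over the list alone. The complement median was 0.46 (0.48 with slide as a block, 0.42 within slide 3), with adjusted p = 9.80e-10, and adjusted p = 0.0147 with an estimated correlation. This was the 1 list in any comparison that kept its call with an estimated correlation. Macrophage and monocyte markers had 0 of 24 members higher and 0 lower over all genes, and 4 and 0 adjusted over the list alone. The macrophage median was 0.24 (0.35 with slide as a block, 0.33 within slide 3), with adjusted p = 4.03e-05, and adjusted p = 0.531 with an estimated correlation. Interferon response genes had 0 of 28 members higher and 0 lower over all genes, and 4 and 0 adjusted over the list alone. The interferon median was 0.24 (0.38 with slide as a block, 0.53 within slide 3), with adjusted p = 8.12e-05, and adjusted p = 0.531 with an estimated correlation. The interferon score was 0.23 and 0.28 in month 1 samples 1 and 5, which nearly coincide, but -0.33 to -0.067 in samples 2 to 4. Sham 7 and 9, which nearly coincide, lay at -0.63 and -0.60, and the other shams at -0.27 to -0.0082. Gene values in month 1, none past the threshold, were 1.86 ± 0.44 for S100a8 (adjusted p = 0.108, 5 of 5 arrays above every sham), 1.46 ± 0.26 for Ccl8 (0.0644), 0.63 ± 0.14 for Sfrp1 (0.108) and 0.81 ± 0.17 for Oasl2 (0.0730).

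Chemokine, fibroblast and epicardial lists were also called higher in month 1, and endothelial and endoplasmic reticulum lists lower. Chemokine, cytokine and acute inflammation genes had a median of 0.18 (0.18 with slide as a block, 0.23 within slide 3), with adjusted p = 0.00439, and adjusted p = 0.441 with an estimated correlation. Fibroblast markers had a median of 0.23 (0.24 with slide as a block, 0.23 within slide 3), with adjusted p = 0.00439, and adjusted p = 0.678 with an estimated correlation. Epicardial and mesothelial markers had a median of 0.58 (0.088 with slide as a block, -0.31 within slide 3), with adjusted p = 0.0103, and adjusted p = 0.866 with an estimated correlation. Endothelial markers had a median of -0.13 (-0.018 with slide as a block, 0.074 within slide 3), with adjusted p = 0.00335, and adjusted p = 0.531 with an estimated correlation. Endoplasmic reticulum stress genes had a median of -0.15 (-0.075 with slide as a block, -0.0092 within slide 3), with adjusted p = 0.0105, and adjusted p = 0.531 with an estimated correlation. Epicardial and mesothelial markers had adjusted p = 0.155 without month 1 sample 4, and endothelial markers 0.542 with slide as a block. No member of these 5 lists passed over all genes. The gene count was 0 in limma (1509 genes at an unadjusted p under 0.05), 0 with close arrays averaged (1403) and with slide as a block (1156), 86 within slide 1, which holds 1 month 1 array, 1 with normexp and 603 with array weights. It was 40 without Sham 8, 11 without month 3 sample 4, 6 without month 2 sample 2, 5 without month 1 sample 5, and 1 without month 1 sample 1 or 2. The list count of 8 became 13 without month 1 sample 3 and 14 without sample 5. The median and the test or mean differed in sign for respiratory chain, apoptosis, atrial, adipocyte and circadian clock genes, none of them called.

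In month 2 the inflammatory rise came with rises in genes of the hypertrophy list. S100a8 rose by 2.87 ± 0.44 (adjusted p = 0.00100, 5 of 5 arrays above every sham), Ccl8 by 2.37 ± 0.26 (adjusted p = 5.66e-05), Hmox1 by 1.08 ± 0.14 and Sfrp1 by 1.02 ± 0.14. Fhl1 rose by 1.27 ± 0.21, Chil1 by 2.64 ± 0.47 and Syt13 by 3.17 ± 0.66. Acta1 stood at the threshold (2.27 ± 0.76, adjusted p = 0.0485, 3.42 ± 1.11, adjusted p = 0.0540 with slide as a block, 1.96 ± 0.86, adjusted p = 0.209 with close arrays averaged, past it in 9 of 24 settings with 1 array left out). Myh7 did not pass (2.01 ± 0.73, adjusted p = 0.0627). Urah (-2.02 ± 0.44) and Aqp1 (-1.48 ± 0.30) fell. So did Aqp4, another water channel (-2.19 ± 0.55), Kcna1 (-1.76 ± 0.50) and Angpt1 (-1.62 ± 0.41), though Aqp4, Kcna1 and Angpt1 did not pass without month 2 sample 1 (adjusted p up to 0.0708).

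In total 1846 genes changed in month 2, 779 up and 1067 down (117 and 52 at least 2-fold), but 6 with close arrays averaged. Those 6, named after their values were seen, were Ccl8, Hmox1, the apolipoprotein gene Apod (1.18 ± 0.16, adjusted p = 0.0166 averaged), Emc10 (1.07 ± 0.13) and Serpina3i (1.50 ± 0.19), which rose, and Gpatch8 (-0.71 ± 0.087), which fell. S100a8 then stood at 2.71 ± 0.48, adjusted p = 0.0513. The count was 1218 with slide as a block (793 shared), 0 within slide 3 alone (limma, 715 at an unadjusted p under 0.05), 889 without the filter, and 712, 1090, 1133 and 1216 without month 2 sample 1, 3, 4 or 5. The share higher was 42.2%, and 52.4% with normexp.

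In month 2, 13 lists were called higher and 3 lower (16, and 13 with close arrays averaged), none with an estimated correlation. The hypertrophy, collagen, fatty acid and hypoxia lists among them followed the 2 levels of Myh7. Hypertrophy and fetal program genes had 6 of 17 members higher and 0 lower over all genes, and 13 and 0 adjusted over the list alone. The hypertrophy median was 1.33 (2.25 with slide as a block, 1.68 within slide 3), with adjusted p = 3.30e-07, and adjusted p = 0.521 with an estimated correlation. Collagen and matrix genes had 4 of 38 members higher and 1 lower over all genes, and 5 and 1 adjusted over the list alone. The collagen median was 0.65 (0.98 with slide as a block, 0.94 within slide 3), with adjusted p = 0.000167, and adjusted p = 0.674 with an estimated correlation. Fatty acid uptake and oxidation genes had 0 of 40 members higher and 7 lower over all genes, and 0 and 9 adjusted over the list alone. The fatty acid median was -0.35 (-0.61 with slide as a block, -0.56 within slide 3), with adjusted p = 0.000297, and adjusted p = 0.674 with an estimated correlation. Chemokine, cytokine and acute inflammation genes had a median of 0.45 (0.35 with slide as a block, 0.82 within slide 3), with adjusted p = 0.000242, and adjusted p = 0.281 with an estimated correlation. Macrophage and monocyte markers had a median of 0.35 (0.43 with slide as a block, 0.65 within slide 3), with adjusted p = 0.000297, and adjusted p = 0.660 with an estimated correlation. Matrix crosslinking and remodelling enzymes had a median of 0.35 (0.58 with slide as a block, 0.45 within slide 3), with adjusted p = 0.000297, and adjusted p = 0.660 with an estimated correlation. Complement and antigen presentation genes had a median of 0.29 (0.34 with slide as a block, 0.36 within slide 3), with adjusted p = 0.000575, and adjusted p = 0.281 with an estimated correlation. Cell cycle genes had a median of 0.39 (0.78 with slide as a block, 0.73 within slide 3), with adjusted p = 0.00707, and adjusted p = 0.674 with an estimated correlation. Interferon response genes had a median of 0.16 (0.36 with slide as a block, 0.22 within slide 3), with adjusted p = 0.0144, and adjusted p = 0.674 with an estimated correlation. As small a p for the interferon list came from 32 of 100 splits, and its score was -0.092 to 0.047 in month 2 and -0.27 to -0.0082 in 8 shams, while Sham 7 and 9, which nearly coincide, lay at -0.63 and -0.60. The other 7 called lists each lost the call when 1 array was left out, and their adjusted p was 0.281 to 0.735 with an estimated correlation. The value in brackets is the highest adjusted p that leaving out 1 array gave. TGF-beta and BMP pathway genes had a median of 0.25 (0.0643 without month 2 sample 5). Glucose uptake and glycolysis genes had a median of 0.12 (0.0611 without month 2 sample 3). Citric acid cycle genes had a median of -0.13 (0.208 without month 2 sample 5). Respiratory chain and ATP synthase genes had a median of -0.16 (0.281 without month 2 sample 5). Antioxidant and oxidative stress genes had a median of 0.033 (0.0859 without month 2 sample 2). Hypoxia and angiogenesis genes had a median of 0.14 (0.0578 without month 2 sample 2). Fibroblast markers had a median of 0.13 (0.0643 without month 2 sample 5). For atrial and adipocyte markers, neither called, the median and the test or mean differed in sign.

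Month 3 had the most changed genes, and interferon targets were among those that rose. Ifit1 rose by 2.43 ± 0.23 (adjusted p = 9.62e-08, 4 of 4 arrays above every sham), B2m by 0.92 ± 0.12 and H2-D1 by 1.00 ± 0.14. Hdc rose by 1.97 ± 0.19 (adjusted p = 1.05e-07), Hmmr by 1.66 ± 0.17, Cdkn1a by 1.93 ± 0.28 and Fbln2 by 1.26 ± 0.17. S100a8 (2.87 ± 0.47) and Ccl8 (1.83 ± 0.28) were also raised. Postn (1.88 ± 0.63, adjusted p = 0.0225) and Myh7 (2.07 ± 0.78, 0.0408) passed, but not with close arrays averaged (Postn 1.97 ± 0.71, adjusted p = 0.0596, Myh7 1.84 ± 0.86, adjusted p = 0.134) or without month 3 sample 4 (adjusted p = 0.0756 and 0.0952). Aqp1 (-1.80 ± 0.32), Kcnd2 (-1.54 ± 0.25), Adrb1 (-1.24 ± 0.20) and Etfdh (-0.80 ± 0.13) fell.

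Among the largest rises of month 3 were genes of multicopy families. Orly was at least 16.5-fold higher than in sham (adjusted p = 1.96e-10) and Ssty2 at least 3.74-fold (5.29e-05), both Y-linked families of male germ cells, and the olfactory receptor gene Olfr39 at least 8.35-fold (1.25e-08); none was well above background in any sham. Whether these probes match elsewhere in the genome was not checked. Sly, of the same Y-linked kind, rose by 4.26 ± 0.56 and was above background in 3 of 10 shams. Probes that hold a simple sequence repeat, 324 of them kept, were raised as a class in month 3. Of these 101 of 324 (31.2%) rose at least 2-fold against 1558 of 20714 other probes (7.52%). Their median change was 0.61 (0.70 with slide as a block) against 0.033. Their median lay at -0.59 to -0.82 in month 3 samples 2 to 4 and at -1.40 in sample 1, against -1.82 to -1.37 in sham.

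**Figure D3:**
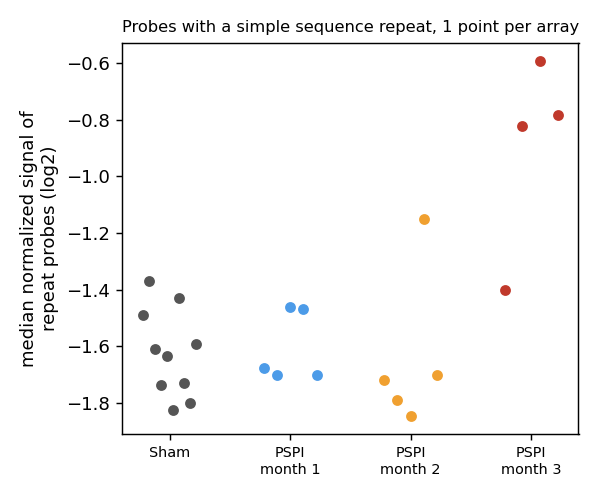
Median normalized signal (log2, vertical axis) of the kept probes with a simple sequence repeat in each array, grouped as sham and PSPI months 1 to 3, 1 point per array. Month 3 samples 2 to 4 (-0.82, -0.59 and -0.78) and month 2 sample 4 (-1.15) lie above the highest sham (-1.37).

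Mesothelin, Msln, a marker of the heart's outer lining, fell in month 3 by 4.18 ± 0.86 (adjusted p = 0.000767, 1 of 4 month 3 arrays above background). The amino acid transporter gene Slc38a5 (-2.65 ± 0.51) and the eosinophil chemokine Ccl11 (-2.81 ± 0.71) fell too. The mucin Muc16 (-3.18 ± 0.94), Retnla (-2.53 ± 0.67) and adipsin, Cfd (-2.51 ± 0.84), passed in the 24 arrays but not with close arrays averaged (Muc16 -2.65 ± 1.11, adjusted p = 0.0969, Retnla -2.32 ± 0.82, adjusted p = 0.0533, Cfd -1.74 ± 0.97, adjusted p = 0.201), and Cfd not without month 3 sample 4 (0.101). Epicardial and mesothelial markers as a list did not pass (median -0.40, adjusted p = 0.532), nor did atrial cardiomyocyte markers (-0.73, 0.258).

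Of the genes tested 4754 changed in month 3, 2224 up and 2530 down, of which 636 and 188 at least 2-fold. With close arrays averaged 2694 changed (2685 shared), with slide as a block 3908 (3618 shared), within slide 3 alone 1574 (1524 shared), and without genes of repeat, multicopy or clone kind 4202. The share higher was 46.8%, but 26.6% with the percentile over all probes, 31.2% with quantile normalization, 65.7% with normexp, 67.5% in the deposited table and 61.3% without the filter. The median of all genes, -0.025 as scaled, moved to -0.16, -0.12, 0.10, 0.12 and 0.29 under these, so small shifts are relative to that scale; no named gene past the threshold turned its direction.

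Interferon response genes had 22 of 28 members higher and 0 lower over all genes, and 23 and 1 adjusted over the list alone. The interferon median was 0.73 (0.81 with slide as a block, 0.95 within slide 3), with adjusted p = 7.82e-10, and adjusted p = 0.251 with an estimated correlation. Neutrophil and mast cell markers had 5 of 7 kept members higher and 0 lower over all genes. Adjusted over the list alone these were 5 and 0. The neutrophil median was 1.31 (1.33 with slide as a block, 1.53 within slide 3), with adjusted p = 0.000736, and adjusted p = 0.0725 with an estimated correlation. Fatty acid uptake and oxidation genes had 1 of 40 members higher and 21 lower over all genes, and 2 and 23 adjusted over the list alone. The fatty acid median was -0.53 (-0.65 with slide as a block, -0.52 within slide 3), with adjusted p = 0.000271, and adjusted p = 0.708 with an estimated correlation. Endothelial markers had 10 of 24 members higher and 1 lower over all genes, and 12 and 2 adjusted over the list alone. The endothelial median was 0.24 (0.33 with slide as a block, 0.35 within slide 3), with adjusted p = 0.00677, and adjusted p = 0.708 with an estimated correlation, although Aqp1 of that list fell. Complement and antigen presentation genes had a median of 0.63 (0.73 with slide as a block, 0.68 within slide 3), with adjusted p = 0.000933, and adjusted p = 0.251 with an estimated correlation. Macrophage and monocyte markers had a median of 0.38 (0.40 with slide as a block, 0.29 within slide 3), with adjusted p = 0.00313, and adjusted p = 0.708 with an estimated correlation. The other 10 called lists each lost the call when 1 array was left out, and their adjusted p was 0.251 to 0.751 with an estimated correlation. The value in brackets is the highest adjusted p that leaving out 1 array gave. Hypertrophy and fetal program genes had a median of 1.14 (0.0799 without month 3 sample 1). Calcium handling and ion channel genes had a median of -0.36 (0.104 without month 3 sample 4). Collagen and matrix genes had a median of 0.44 (0.230 without month 3 sample 4). Matrix crosslinking and remodelling enzymes had a median of 0.32 (0.0969 without month 3 sample 4). TGF-beta and BMP pathway genes had a median of 0.38 (0.150 without month 3 sample 1). Citric acid cycle genes had a median of -0.29 (0.119 without month 3 sample 4). Antioxidant and oxidative stress genes had a median of 0.19 (0.101 without month 3 sample 3). Apoptosis and p53 target genes had a median of 0.38 (0.0799 without month 3 sample 1). Cell cycle genes had a median of 0.51 (0.190 without month 3 sample 4). Chemokine, cytokine and acute inflammation genes had a median of 0.45 (0.101 without month 3 sample 1). The hypertrophy, collagen, fatty acid, calcium handling and apoptosis lists followed the 2 levels of Myh7. Without month 3 sample 1 the list count fell from 16 (13 higher, 3 lower) to 8, and it stayed 16 with close arrays averaged. The median and the test or mean differed in sign for adipocyte, neuronal and circadian clock genes, none of them called.

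**Figure D4:**
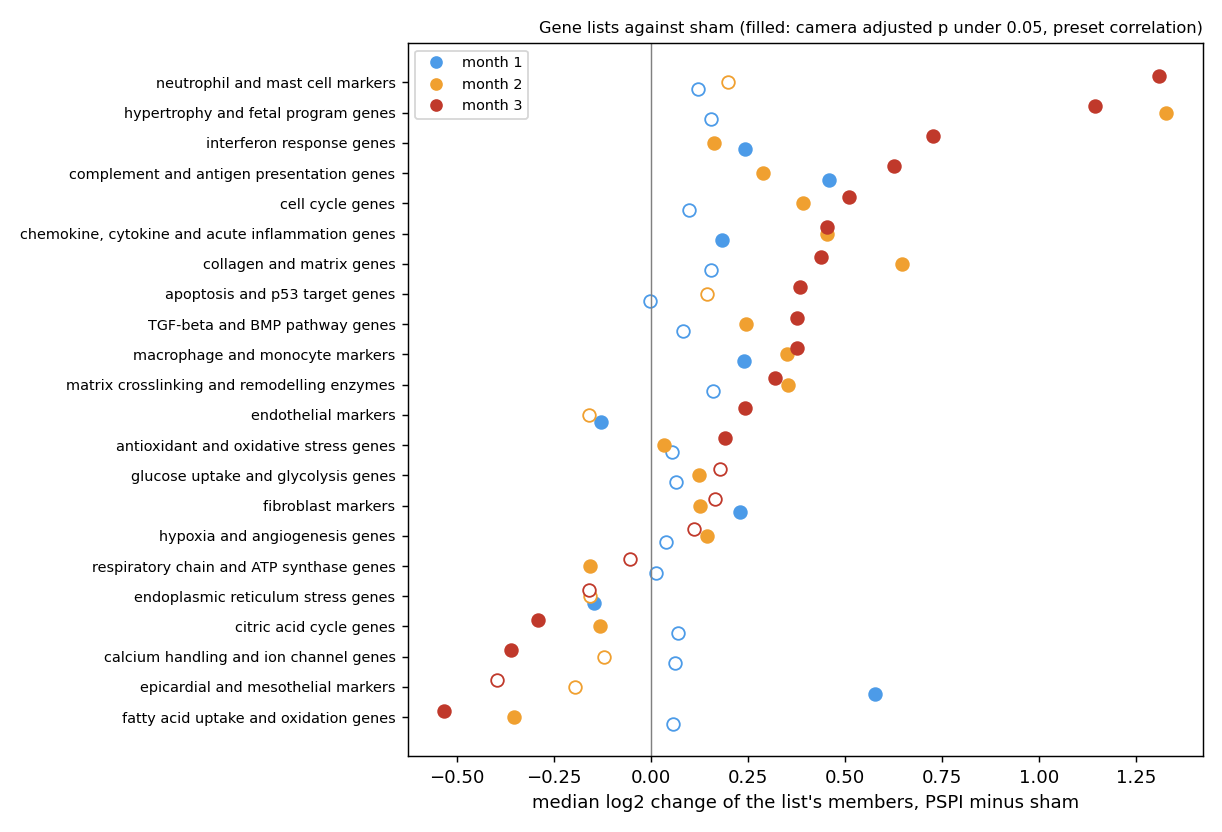
Median log2 change against sham (horizontal axis) of each gene list called in at least 1 month, coloured by month; filled points passed camera's test with the preset correlation and open points did not. Hypertrophy and fetal program genes stand at 0.15, 1.33 and 1.14 in months 1, 2 and 3, and interferon response genes at 0.24, 0.16 and 0.73.

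Differences between the months were tested directly. Interferon genes were higher in month 3 than in month 2: Ifit1 by 1.72 ± 0.26 (adjusted p = 0.000103), H2-D1 by 0.70 ± 0.16 and Oasl2 by 1.01 ± 0.21. Interferon response genes as a list had 16 of 28 members higher and 0 lower over all genes, and 20 and 0 adjusted over the list alone. The interferon median was 0.70 (0.62 with slide as a block, 1.06 within slide 3), with adjusted p = 5.11e-08, and adjusted p = 0.481 with an estimated correlation. Hmmr rose by 1.61 ± 0.19 and Hdc by 1.70 ± 0.21. Acot3, a peroxisomal acyl-CoA thioesterase, and Rsph4a, a component of cilia, were at least 10.8-fold and 6.06-fold higher than in month 2, where no array had them above background (adjusted p = 7.20e-08 and 1.34e-06), beside Orly (4.92 ± 0.40), Sly (4.48 ± 0.63) and Olfr39 (4.25 ± 0.43). The platelet genes Ppbp (-3.23 ± 0.74) and Gp9 (-2.98 ± 0.75) fell. They no longer passed with close arrays averaged (Ppbp -2.77 ± 0.94, adjusted p = 0.0818, Gp9 -2.61 ± 0.96, adjusted p = 0.107), nor did Gp9 with slide as a block (-2.88 ± 0.88, adjusted p = 0.0521).

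A further 4 lists were called between months 3 and 2, 5 in all and 6 with close arrays averaged. Endothelial markers had a median of 0.35 (0.27 with slide as a block, 0.40 within slide 3), with adjusted p = 0.000108, and adjusted p = 0.481 with an estimated correlation. Neutrophil and mast cell markers had a median of 0.39 (0.38 with slide as a block, 0.77 within slide 3), with adjusted p = 0.0170, and adjusted p = 0.387 with an estimated correlation. T cell and NK cell markers had a median of 0.64 (0.40 with slide as a block, 1.03 within slide 3), with adjusted p = 0.0170, and adjusted p = 0.481 with an estimated correlation. Erythroid and blood cell markers had a median of -0.44 (-0.26 with slide as a block, -0.75 within slide 3), with adjusted p = 0.0258, and adjusted p = 0.980 with an estimated correlation. The T cell list lost the call without month 3 sample 2 (0.0519) and the erythroid list without month 2 sample 1 or 4 or month 3 sample 3 (up to 0.0834). Between these months 2279 genes differed, 1177 higher and 1102 lower in month 3. The count was 980 with close arrays averaged (976 shared), 887 with slide as a block (877 shared), 190 within slide 3, 1283 with normexp, 33 within slide 2, which holds 1 month 3 array, and 1849 without repeat and multicopy genes. It was 1381 without month 3 sample 3 and 3637 without sample 1. The median and the test or mean differed in sign for beta-adrenergic, glycolysis, endoplasmic reticulum, macrophage, adipocyte and neuronal genes, none of them called.

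Month 3 against month 1 gave 3480 genes, 1570 higher and 1910 lower, 2451 with close arrays averaged (2329 shared), 2194 with slide as a block, 99 within slide 3, which holds 1 month 1 array, 1200 within slide 2, which holds 1 month 3 array, and 3042 without repeat and multicopy genes. Syt13 (3.25 ± 0.81), Ifit1 (1.70 ± 0.26), Fbln2 (1.17 ± 0.19) and the transcription factor gene Pou3f1 (2.40 ± 0.28) were higher in month 3, and Msln (-5.01 ± 0.98, adjusted p = 0.000820), Muc16 (-4.06 ± 1.07) and Kcnd2 (-1.39 ± 0.29) lower. The atrial light chain Myl7 (-6.57 ± 2.22, adjusted p = 0.0310), sarcolipin, Sln (-6.29 ± 2.11, 0.0298), and Myl4 (-4.54 ± 1.69, 0.0473) were lower too. Myl7 was above background in 1 and Sln in 3 of 4 month 3 arrays, and Msln and Muc16 in 1, so these differences are limited by background. With slide as a block the differences were as large but did not pass: Myl7 -6.96 ± 2.49, adjusted p = 0.0577, Sln -6.77 ± 2.35, adjusted p = 0.0510 and Myl4 -5.01 ± 1.87, adjusted p = 0.0674. Averaged, Sln (-5.76 ± 2.03, adjusted p = 0.0568) and Myl4 (-4.15 ± 1.65, adjusted p = 0.0864) did not pass. Without month 1 sample 2 the adjusted p was 0.0733 for Myl7 and 0.108 for Myl4, and without month 3 sample 3 0.0837 for Sln. Month 1 samples spread from -3.82 to 2.20 in Myl7.

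By list, interferon, endothelial and neutrophil genes were higher in month 3 than in month 1, and fatty acid and calcium handling genes lower. Interferon response genes had a median of 0.44 (0.41 with slide as a block, 0.38 within slide 3), with adjusted p = 4.92e-06, and adjusted p = 0.818 with an estimated correlation. Endothelial markers had a median of 0.50 (0.44 with slide as a block, 0.33 within slide 3), with adjusted p = 5.79e-05, and adjusted p = 0.640 with an estimated correlation. Neutrophil and mast cell markers had a median of 1.01 (1.10 with slide as a block, 1.21 within slide 3), with adjusted p = 0.00456, and adjusted p = 0.266 with an estimated correlation. Fatty acid uptake and oxidation genes had a median of -0.56 (-0.46 with slide as a block, 0.012 within slide 3), with adjusted p = 7.60e-05, and adjusted p = 0.832 with an estimated correlation. Calcium handling and ion channel genes had a median of -0.40 (-0.34 with slide as a block, -0.088 within slide 3), with adjusted p = 0.00209, and adjusted p = 0.832 with an estimated correlation. The fatty acid, calcium handling and apoptosis lists followed the 2 levels of Myh7. Another 2 lists were called and lost the call when 1 array was left out, both with adjusted p = 0.832 with an estimated correlation. Citric acid cycle genes had a median of -0.33 (0.0580 without month 3 sample 1). Apoptosis and p53 target genes had a median of 0.31 (0.117 without month 3 sample 1). The list count of 7 was 13 with close arrays averaged, 11 without month 1 sample 1 and 12 without sample 5. In Wnt, endoplasmic reticulum, complement and adipocyte genes, none of them called, the median and the test or mean differed in sign.

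Month 2 against month 1 gave 2 genes, Pou3f1 (up by 1.62 ± 0.26, adjusted p = 0.0187) and the unnamed clone C80140, which was lower and was chosen after its values were seen, as the count is small. The count was 0 with close arrays averaged (Pou3f1 1.61 ± 0.27, adjusted p = 0.193, 1551 at an unadjusted p under 0.05), with normexp (1153), and in the deposited table (1133). It was also 0 without month 1 sample 2, 3 or 4 or month 2 sample 1 or 5, and 6 or 4 without month 2 sample 2 or 4. In limma 1602 genes had an unadjusted p under 0.05. Within slide 2 alone 1303 genes differed, but its 3 month 1 arrays are those at the lower Myh7 level and its 4 month 2 arrays are at the higher. Between these months the hypertrophy list was higher and the fatty acid and epicardial lists lower. Hypertrophy and fetal program genes had a median of 1.17 (1.38 with slide as a block), with adjusted p = 6.65e-08, and adjusted p = 0.680 with an estimated correlation. Fatty acid uptake and oxidation genes had a median of -0.34 (-0.42 with slide as a block), with adjusted p = 1.42e-06, and adjusted p = 0.680 with an estimated correlation. Matrix crosslinking and remodelling enzymes had a median of 0.26 (0.32 with slide as a block), with adjusted p = 0.000261, and adjusted p = 0.680 with an estimated correlation. Collagen and matrix genes had a median of 0.38 (0.46 with slide as a block), with adjusted p = 0.000468, and adjusted p = 0.680 with an estimated correlation. Citric acid cycle genes had a median of -0.22 (-0.28 with slide as a block), with adjusted p = 0.000487, and adjusted p = 0.680 with an estimated correlation. Epicardial and mesothelial markers had a median of -0.78 (-1.01 with slide as a block), with adjusted p = 0.000876, and adjusted p = 0.680 with an estimated correlation. Immediate early genes had a median of 0.46 (0.56 with slide as a block), with adjusted p = 0.00106, and adjusted p = 0.680 with an estimated correlation. Cell cycle genes had a median of 0.25 (0.38 with slide as a block), with adjusted p = 0.00305, and adjusted p = 0.680 with an estimated correlation. The hypertrophy, fatty acid, collagen, calcium handling, hypoxia and apoptosis lists followed the 2 levels of Myh7. In all 13 lists were called (12 with close arrays averaged), 8 higher and 5 lower, 8 of them whichever array was left out. The others had an adjusted p of 0.680 to 0.761 with an estimated correlation. The value in brackets is the highest adjusted p that leaving out 1 array gave. Calcium handling and ion channel genes had a median of -0.25 (0.199 without month 1 sample 4). Respiratory chain and ATP synthase genes had a median of -0.17 (0.425 without month 1 sample 3). Hypoxia and angiogenesis genes had a median of 0.12 (0.0567 without month 1 sample 5). Apoptosis and p53 target genes had a median of 0.074 (0.133 without month 1 sample 3). Chemokine, cytokine and acute inflammation genes had a median of 0.15 (0.0604 without month 1 sample 1). The median and the test or mean differed in sign for sarcomere, endoplasmic reticulum, interferon, fibroblast, skeletal muscle and adipocyte genes, none of them called.

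The F test over the 3 months found 3107 genes that differ among the PSPI months, 1731 with close arrays averaged, 1857 with slide as a block, 2676 without repeat and multicopy genes and 1934 without month 3 sample 3. Across genes, which are not independent replicates, the changes of months 2 and 3 correlated with r = 0.50, months 1 and 2 with 0.48 and months 1 and 3 with 0.24, all against the same shams. Unchanged groups against these shams gave a mean of 0.30, 0.31 and 0.29 in 100 simulations (95% of them within -0.29 to 0.89, -0.39 to 0.85 and -0.32 to 0.78), so none of the 3 observed r lies outside. The simulated mean covariances were 0.014, 0.013 and 0.012, against 0.110, 0.040 and 0.033 observed, a difference of 0.096, 0.027 and 0.022. With the shams split into separate sets the median r was 0.43, 0.36 and 0.15. Months 2 and 3 shared 427 genes higher and 605 lower, and 33 went opposite ways. With close arrays averaged they shared 5 and 1. Independent lists would share 139 and 216, a value that leaves out the shared shams. Unchanged groups against 1 control group hardly passed the threshold, so lists as long as the real ones were taken by smallest p. In 50 simulations these shared a median of 328 higher (49 to 661) and 464 lower (65 to 918), so the observed overlap lies within their range. A median of 66.5 (2 to 683) went opposite ways, against 33 observed. The simulations deal out the arrays' own deviations, with the 2 levels of Myh7 and the close arrays in them. They therefore do not set the effect of shared shams apart. With 5 shams for each month, the medians of 50 draws were 140 shared higher (52 to 307) and 164 lower (35 to 494). Fewer genes were then called, a median of 601 in month 2 and 3844.5 in month 3. A median of 7.5 (0 to 163) went opposite ways. These draws, and the split of the shams used for r, can put nearly coinciding shams in both sets. The sets may therefore still share a sham, and no chance overlap was computed for lists of these lengths.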

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

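The 7 tests of explanations given here were chosen after the result they measure was seen; chance alone sets a sample apart, by the gap rule used, in about 1 in 20 groups, and 16 of 296 groups were set apart.

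Myh7 took 2 levels that cross the labels, with a gap of 2.15 log2 between 9 and 15 arrays, and Gdf15 (3.13), Ankrd1 (1.07) and Postn (0.85) parted the same arrays, Gdf15 and Ankrd1 being named after their values were seen. In Acta1 the gap (1.09) left 11 arrays lower, month 3 samples 2 and 3 among them, and the largest gap of Nppb (1.39) set 1 array apart. Slide is argued against, since the 7 shams of slide 1 alone held a gap of 2.56 in Myh7. An exchange of labels between sham and month 1 cannot be told apart from a difference between samples. With close arrays averaged, the labels part 57 genes without overlap. Of 210 ways to give these labels to the sets 6 part as many, a share of 0.0286 that was first meant to decide. But the way that follows the Myh7 levels parts 816, and slide, of which slide 2 holds no sham, was not set apart. Some measures, picked after they were seen, ran as labelled. The complement score was 0.15 to 0.39 in month 1 and at most 0.088 in any sham. S100a8 was -5.07 to -3.11 in month 1 and at most -5.45 in any sham. Atrial tissue is argued against as the whole cause by 4 arrays at the higher Myh7 level with Myl7 not above background (Sham 8 and month 3 samples 1 to 3), while no biological explanation was tested and a difference between animals stays open.

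Probes of repeat sequence, with Orly, Sly, Ssty2 and Olfr39, were brighter at month 3. Slide is argued against, since the median rise of the repeat probes was 0.70 with slide as a block. Genomic DNA in the RNA may contribute but cannot be told apart from a change in transcription: 1 month 3 array (sample 4, 13.4%) had a higher share of the 1198 olfactory receptor probes above background than any sham (1.67% to 5.01%), and the other 3 had 2.92%, 4.26% and 3.92%. Brightness of the array is also open, since of the 2 month 3 arrays as bright as shams 1 had raised repeat probes, while the dim month 2 sample 4 had them too. Month 1 samples 3 and 4 and month 2 sample 3 were also dimmer than any sham (75th percentile 1194, 1514 and 1628, lowest sham 1780). Their repeat medians of -1.46, -1.47 and -1.85 did not exceed the highest sham (-1.37). A response of the tissue at month 3 and matches of these probes elsewhere in the genome were not tested.

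Arrays of a group nearly coincided in 8 of 276 pairs. The same RNA on more than 1 array may account for this, and the lowest ratio of a pair's spread to the spread between spots, 1.42, does not decide it, because labelling RNA again adds a spread that was not measured here. Tissue of 1 animal in several samples would leave the same closeness and was not tested, and separate animals that resemble each other were not tested either. With such arrays averaged, 771 genes changed over all months, 6 in month 2 and 2694 in month 3.

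Single samples lay far from their group in these genes, each with the gap as a share of the group's range. S100a8 was lowest in month 3 sample 4 (0.930), as was S100a9 (0.897), and S100a9 was lowest among shams in Sham 10 (0.525). Ifitm3 was highest in Sham 8 (0.475) and Orly in Sham 2 (0.476). In month 1, Serpina3n was highest in sample 4 (0.786), Hdc in sample 3 (0.711), Ndrg1 in sample 1 (0.770) and Slc38a5 in sample 2 (0.747), and Hmox1 was lowest in sample 5 (0.885). In month 2, Ssty2 (0.727) and Muc16 (0.804) were highest in sample 4. In month 3, Hmox1 (0.982) and Gp9 (0.870) were highest in sample 1, and Myl7 (0.859) and Myl4 (0.876) in sample 4.

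Months differed by direct tests in 2 genes (month 2 against month 1), 2279 (month 3 against month 2), 3480 (month 3 against month 1) and 3107 (any month). Of 5161 probes with no gene symbol, which enter no comparison above, 1290 changed over all months, 925 higher and 365 lower.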

How the results depend on the processing

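The percentile over all probes, averaging of close arrays, leaving out month 3 and leaving out repeat and multicopy genes were chosen after seeing the data. Over all alternatives, named genes kept their side of the threshold in 10120 values, lost the call in 804 and gained it in 153. Values called in either fit that turned direction numbered 0. For lists these were 7411, 220, 176 and 5. A turn of direction in a value called in neither fit was not counted and lies within the first number. Probes near background limit small values, and the cause of the differences below was not tested except that slide 3 alone, averaging and the groups of 1 contrast use fewer samples, and every kept probe tests more. Over all months (3043) the count was 4927 with every kept probe, 4954 with array weights, 1984 with slide as a block, 0 within slide 3, 771 with close arrays averaged and 1179 without month 3. In month 1 (0) it was 1 with normexp, 1 in the deposited table, 2 with probes on all arrays, 603 with array weights, 2 within slide 3 and 4 with only the groups compared. In month 2 (1846) it was 889 without the filter, 4337 with array weights, 1218 with slide as a block, 0 within slide 3 and 6 averaged. In month 3 (4754) it was 8300 with every kept probe, 1574 within slide 3 and 2694 averaged. For month 2 against month 1 (2) it was 0 with normexp, without the filter, with probes on all arrays, in the deposited table and averaged, 2050 with array weights and 1 within slide 3 (1 array against 1). For month 3 against month 2 (2279) it was 1283 with normexp, 1293 in the deposited table, 4699 with every kept probe, 5082 with array weights, 887 with slide as a block, 190 within slide 3, 980 averaged and 1175 with only the groups compared. For month 3 against month 1 (3480) it was 2275 with normexp, 2251 in the deposited table, 6201 with every kept probe, 5661 with array weights, 2194 with slide as a block, 99 within slide 3 and 1767 with only the groups compared. For any month (3107) it was 1779 with normexp, 1782 in the deposited table, 5785 with every kept probe, 6991 with array weights, 1857 with slide as a block, 189 within slide 3 and 1731 averaged. Lists called with an estimated correlation were 1 in month 1 (8) and 0 in each other comparison (15 over all months, 16 in months 2 and 3, 13, 5 and 7 between months). Lists in month 1 numbered 14 with slide as a block and 15 averaged, in month 3 10 with normexp, and for month 3 against month 1 13 averaged. In month 1 the fatty acid list went to -0.22 and the respiratory chain list to -0.070 with slide as a block. With 1 array left out the respiratory chain list ran from -0.099 (without PSPI_1month replicate 3) to 0.12 (without PSPI_1month replicate 5). None of these was a call in the 24 arrays.

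With each array left out in turn, counts ran from 2451 to 3508 over all months, 0 to 40 in month 1, 712 to 2401 in month 2, and 3478 to 5322 in month 3. They ran from 0 to 6 for month 2 against month 1, 1381 to 3637 for month 3 against month 2, 2388 to 4361 for month 3 against month 1 and 1934 to 4176 for any month. Lists ran from 13 to 17 over all months, 8 to 14, 11 to 18 and 8 to 17 in months 1 to 3, and 9 to 16, 4 to 7 and 5 to 12 between months. With the replicate number as a block (5 shams left out, since their numbers have no partner) counts were 86 in month 1, 3032 in month 2 and 80 for month 2 against month 1. The shams left out, Sham 6 to 10, include all 4 at the higher Myh7 level. Every sham kept stood at the lower level, so the effect of the block is not set apart from that of leaving these out. Lists with the replicate block numbered 13 in month 1 and 11 for month 3 against month 1, and the month 1 lists of fatty acid and immediate early genes went to -0.18 and 0.47. Samples with the same number did not deviate together on average: over 27 pairs the mean correlation was 0.016 (-0.45 to 0.52), against -0.0030 for different numbers. The 2 levels of Myh7 enter these correlations as well, so a pairing by number is not excluded.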

Other observations

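Genes outside the fixed rule were looked at after their values were seen. The stress cytokine gene Gdf15 lay between -4.85 and -4.37 on 9 arrays and between -1.24 and 1.67 on 15. Cpt1b, which admits fatty acids to mitochondria, stood at 0.25 in month 1 sample 1 and at 2.06 in the nearly coinciding month 1 sample 5. Myl7 was near 3.5 in Sham 3, 4 and 10 (3.54, 3.50 and 3.55). Xist, the noncoding RNA of the silent X chromosome, stood at -4.57 in month 1 sample 2 and between -9.74 and -7.25 on the other arrays, while the Y-linked Ddx3y lay between -1.74 and -1.05 on all 24.

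The split tests were chosen before their results were seen. Those of single lists were added after the number of lists had been seen, and those of averaged arrays, except over all months and in month 3, after the splits of the 24 arrays. Each counts splits of the same arrays into groups of the same sizes, the real one included, 100 unless a number is given. None sets slide apart. The 8 close pairs lie within groups, and splits of the 24 arrays can part them, which the real labels never do. Counts of such splits, those for lists included, therefore cannot exclude chance by themselves. For the count over all months 1 split gave as many genes (3043 real, 99 the highest other). Averaged, 2 did (771, 1104), under the limit used, although another split gave more. For month 1 the real count is 0 with and without averaging, which each of 100 splits reaches, so the splits decide nothing (highest other 11, and averaged 2058). For month 2 2 splits gave as many (1846, 2006). Averaged, 1 did (6, 1), so chance can be excluded for the count of 6 but not for that of 1846. For month 3 1 did (4754, 3140), and averaged 1 of 84 (2694, 1191), so chance can be excluded for the latter.

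Between months, 4 splits gave as many for month 2 against month 1 (2, 236), just under the limit used. These splits can part close arrays and the count is 2 genes, so chance is not excluded. Averaged, the real count is 0, which 35 of 35 splits reach, so they decide nothing (highest other 1). For month 3 against month 2, 2 did (2279, 2916), and averaged 2 of 35 (980, 1082). For month 3 against month 1, 1 did (3480, 2557), and averaged 2 of 35 (2451, 2760). Chance is thus not excluded for either: the averaged shares are over the limit used, and splits of 24 arrays can part close arrays. For any month 1 did (3107, 2323), and averaged 1 (1731, 1031), so chance can be excluded for the latter.

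Some splits that gave many genes point to a structure of the samples. In month 2 the split with 2006 put Sham 1, 3, 4, 5 and 10 together, which keeps the arrays that nearly coincide on 1 side and also follows Myh7, since all 5 stand at its lower level. With close arrays averaged, the split with 2058 in month 1 and that with 2760 for month 3 against month 1 followed the level of Myh7, the first across sham and month 1. The splits with 2916 and 1082 for month 3 against month 2 exchanged month 2 sample 4, the month 2 array with raised repeat probes, for month 3 sample 1, the month 3 array without them. List scores, picked after they were seen, went both ways. The interferon score was 0.47 in month 3 sample 1 (0.50 to 1.17 in samples 2 to 4) and 0.047 in month 2 sample 4 (-0.092 to -0.0075 in the others), as labelled. T cell and NK cell markers stood at -0.13 (0.45 to 0.92) and 0.14 (-0.63 to -0.11), as in an exchange. Whether these 2 labels were exchanged stays open.

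For the number of lists chance cannot be excluded: as many were called in 13 splits over all months (15, 20), 66 in month 1 (8, 19), 9 in month 2 (16, 19) and 20 in month 3 (16, 19). The splits with as small a p were also counted for each called list. Over all months as small a p came from 2 for chemokine, 3 for complement, 3 for neutrophil, 5 for interferon, 9 for antioxidant, 12 for macrophage, 19 for endoplasmic reticulum and 21 for remodelling genes. It came from 23 for hypertrophy, 25 for apoptosis, 28 for TGF-beta, 34 for fatty acid, 37 for collagen, 39 for cell cycle and 44 for citric acid cycle genes. In month 1 as small a p came from 1 for complement, 4 for chemokine, 4 for endothelial, 6 for macrophage, 10 for interferon, 15 for endoplasmic reticulum, 22 for fibroblast and 33 for epicardial genes. In month 2 as small a p came from 4 for chemokine, 6 for hypertrophy, 6 for antioxidant, 7 for hypoxia, 7 for remodelling, 12 for complement, 23 for glycolysis and 23 for macrophage genes. It came from 28 for collagen, 32 for interferon, 33 for TGF-beta, 36 for fatty acid, 36 for fibroblast, 37 for citric acid cycle, 38 for cell cycle and 57 for respiratory chain genes. In month 3 as small a p came from 1 for neutrophil, 7 for interferon, 11 for chemokine, 12 for apoptosis, 14 for complement, 14 for endothelial, 23 for antioxidant and 24 for macrophage genes. It came from 25 for fatty acid, 26 for calcium handling, 27 for remodelling, 33 for cell cycle, 34 for TGF-beta, 35 for hypertrophy, 40 for citric acid cycle and 47 for collagen genes.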
